A study of Mus musculus with 32 samples.

How the data were processed

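RNA was measured in single hemispheres of hippocampus or striatum from male C57BL/6J mice aged 12 weeks. Each mouse received CI-994, an inhibitor of class I histone deacetylases (HDACi, 30 mg/kg), or its solvent (vehicle) by intraperitoneal injection 1 hour before behaviour. Behaviour was contextual fear conditioning (CFC, 2 foot shocks of 0.2 mA in a chamber) or the same time in the chamber without shocks (context), and tissue was taken 1 hour later. Per the labels each library holds 1 region of 1 mouse, so the 4 libraries of a group are 4 mice. The labels do not say whether the hippocampus and the striatum library with the same treatment and replicate number come from 1 mouse. All mice of a cage went through the same behaviour, so cage and behaviour cannot be separated in these data.

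The deposited file holds raw read counts per gene, which the authors made from stranded libraries of polyadenylated RNA. The processing notes name bcl2fastq 2.20.0, STAR 2.6, DESeq2 and the mm10 build, with no role for each tool. The counting step and its strand setting are not given in the sources used here. Values of genes that overlap another gene, or that have near-identical relatives such as the Zfp genes, are therefore uncertain. The counts were whole numbers, and no pair of replicates was a copy (chi-square per degree of freedom from 5.77 to 67.7). Of 54146 gene identifiers, 54079 matched a symbol in GENCODE mouse release M21, from which positions, transcript length and GC content were also taken. The 67 others held at most 0.0264% of a library's counts. Totals per library ran from 26026024 to 36670767 counts in hippocampus and from 27418127 to 33635025 in striatum. Levels of genes are given as CPM, each count relative to the library total with no further scaling. Values in log2 CPM, such as the means of gene lists, are from edgeR with the TMM scaling and the filter described below.

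Each region's 16 libraries were fitted together in R 4.3.3 with edgeR 4.0.16, with 4 group means, TMM scaling, filterByExpr on the groups and the quasi-likelihood F test (two-sided). Adjusted p values follow Benjamini and Hochberg over all genes of a comparison, and genes with adjusted p under 0.05 are called changed. This left 18261 genes in hippocampus and 18256 in striatum. All 32 libraries were fitted together for the region differences and the baseline contrast (19198 genes). Log2 fold changes are HDACi over vehicle, CFC over context, or hippocampus over striatum. An interaction or region difference is a difference of log2 fold changes. The median standard error of a drug effect was 0.135 to 0.138 log2, and 0.096 to 0.097 for genes over 3 log2 CPM. On simulated counts 200 genes with mean log2 CPM of at least 1 were changed, so recovery of genes under that level was not tested. The fits called 86 to 96% of genes changed 2-fold within a region, 54 to 66% at 1.5-fold and 2 to 22% at 1.25-fold. For the interactions these shares were 70 to 72%, 20 to 28% and 0 to 4%. For the region differences they were 72 to 80%, 32 to 42% and 2 to 8%. Of the calls on simulated counts, 1.8 to 7.9% were false. Genes were drawn independently, with no difference between replicate numbers and no GC content trend, so these shares may not hold for the real libraries.

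Before the data were examined, these choices were fixed: the groups, the tests, 33 gene lists (pathways, RNA composition and cell type markers), the first alternatives named below, and the rule for naming genes. A gene is named when it is 1 of 10 chosen genes (Fos, Arc, Npas4, Egr1, Nr4a1, Bdnf, Homer1, Hdac1, Hdac2 and Hdac3). It is also named when it is among the 3 members of a fixed list with the smallest adjusted p under 0.05. Last, it is named when it is among the 8 called genes that rose or fell most, with mean log2 CPM of at least 1, a symbol that is not a clone or predicted-gene name, and no overlap between the 2 groups in TMM-scaled log2 CPM. Genes outside this rule are named only where the text says that they were chosen after their values were seen. Of the list members, 19 were matched through an older symbol. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1, two-sided, preset correlation between genes of 0.01), adjusted over the lists of a comparison. The test was repeated with the correlation estimated from the data.

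The first alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no filter on low counts, a replicate block, only the 2 groups compared, and leaving out each library in turn. Alternatives added after the data were seen were a batch term for replicates 1 and 2 against 3 and 4, only replicates 1 and 2 or only 3 and 4, and offsets for GC content and transcript length. Scaling to library size alone, and a fit without libraries that stood apart, were also added then. A library stood apart when the mean log2 CPM of the choroid plexus list was over 5 in hippocampus, or that of the medium spiny neuron list under 8.2 in striatum. To ask whether libraries with the same number are paired, residuals of genes over 3 log2 CPM were correlated. Within a region, 21 of 24 pairs in hippocampus and 16 of 24 in striatum had r over 0.1, not all, and the main fits hold no pairs. Median r was 0.51 and 0.24 for the same number, against −0.27 and −0.17 for other numbers of other groups. Within replicates 1 and 2 or 3 and 4 it was 0.41 and 0.32, against −0.49 and −0.29 across these sets. The main fits thus leave out a structure shared by the groups, and the replicate block and batch term stand beside them as alternatives. Between the regions all 16 pairs had r over 0.1 (0.13 to 0.84), and 12 of 16 libraries matched best with their own number, so counts with a mouse block are given beside the region results. A difference between replicates 1 and 2 and replicates 3 and 4 that both regions share can raise these values too. They therefore do not show that a pair is 1 mouse. Each grouping was also set against all 35 splits of the 8 libraries compared into groups of 4, or against 50 drawn splits for the interactions. For the region differences of the drug's and of conditioning's effect, 8 pairs were split instead of libraries. Each pair was the hippocampus and striatum library of 1 treatment and number, kept together as if from 1 mouse. No library was left out of the main results.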

Results

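The data are RNA counts from 32 libraries, 16 of hippocampus and 16 of striatum. In each region 4 groups of 4 mice were compared: vehicle or CI-994 (HDACi) injection, followed by fear conditioning (CFC) or by the chamber alone (context). Totals ran from 26026024 to 36670767 counts per library. Over the groups together replicates 1 and 2 differed from replicates 3 and 4, with 6528 genes called between these 2 sets in hippocampus and 3739 in striatum. The split does not hold in every group: replicates 2 and 4 were the closest pair in hippocampus HDACi CFC and in striatum vehicle CFC, and replicates 1 and 3 in striatum HDACi CFC. Counts within each set therefore stand beside the drug results. The contrasts ask what the drug changed after each behaviour, what conditioning changed with and without the drug, and how the regions differed.

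**Figure D1:**
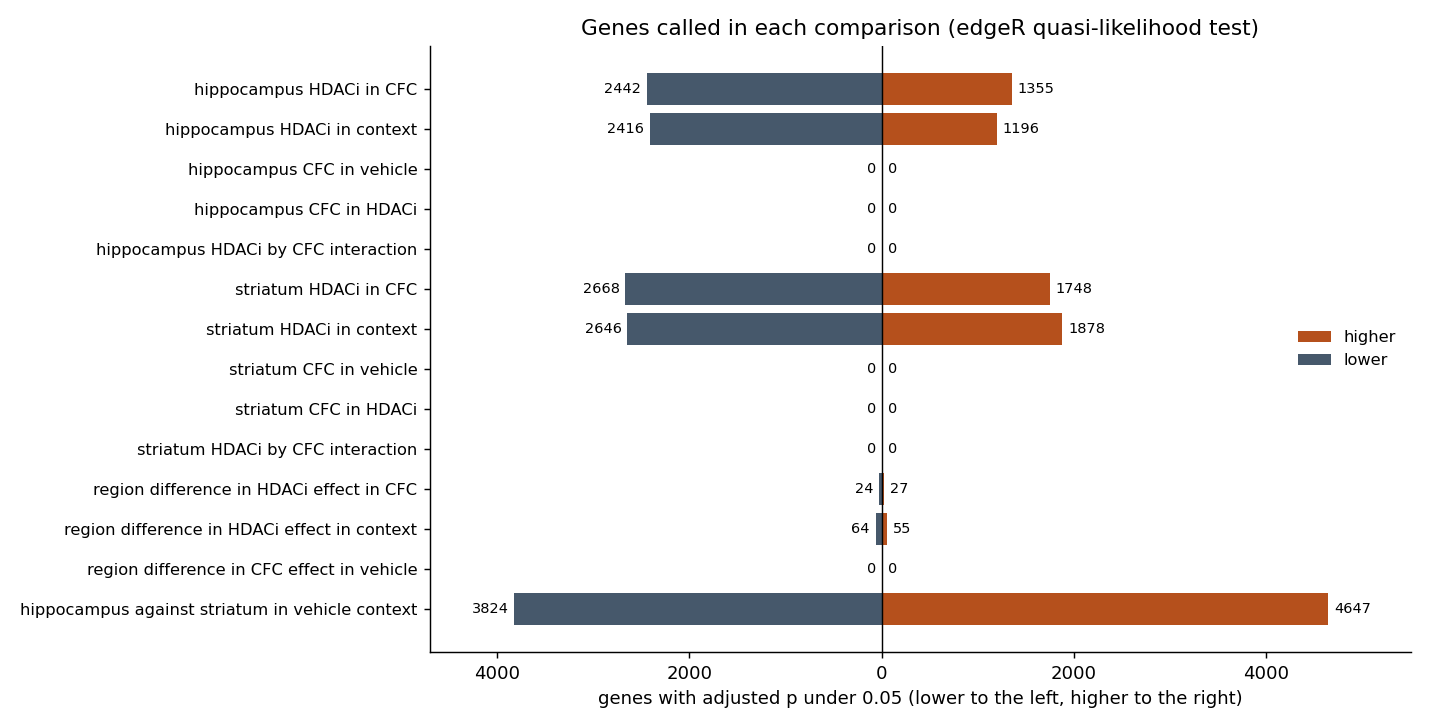
Number of genes with adjusted p under 0.05 in each comparison (horizontal axis, lower to the left and higher to the right, edgeR quasi-likelihood test). The 4 drug comparisons called between 3612 and 4524 genes, and the comparisons of conditioning with context called 0.

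In hippocampus after conditioning, the drug lowered Sirt1, Ing5 and Malt1 over 3-fold and raised Themis2 and Ptgs2 over 2-fold. Sirt1 (ENSMUSG00000020063), which encodes a NAD-dependent deacetylase, fell 3.91-fold, from 22.5 ± 2.21 to 5.51 ± 0.433 CPM (SD, n = 4; log2 fold change −1.97, SE 0.096, adjusted p = 8.13e-09). It lies on mm10 chromosome 10 from 63319005 to 63381704. Ing5, a subunit of histone acetyltransferase complexes, fell 3.65-fold from 18.8 ± 1.35 CPM (SD, n = 4), and Malt1, a paracaspase of NF-kappaB signalling, fell 3.64-fold from 12.9 ± 1.78 CPM. Themis2 (ENSMUSG00000037731), a signalling adaptor of immune cells, rose 4.91-fold to 3.17 ± 0.3 CPM (SD, n = 4). Ptgs2 (ENSMUSG00000032487), the inducible prostaglandin synthase, rose 2.51-fold, from 42.1 ± 8.91 to 101 ± 3.02 CPM (SD, n = 4; adjusted p = 4.08e-05).

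Among the genes of chromatin regulation, 12 of 22 acetyltransferases and acetyl-lysine readers fell and 0 rose, and the counts were the same adjusted over the list alone (median log2 fold change −0.22, camera adjusted p = 0.000871; adjusted p = 0.258 with an estimated correlation). Ep300, a transcriptional acetyltransferase, fell 1.52-fold and the bromodomain gene Brd8 1.48-fold. Of 28 subunits of class I HDAC corepressors, 4 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.275). Sin3a (ENSMUSG00000042557), the scaffold of the Sin3 corepressor, fell 2.03-fold, from 42.7 ± 3.30 to 20.1 ± 1.44 CPM (SD, n = 4), and Rcor3 fell 1.64-fold. Of 11 histone deacetylase genes, 1 fell and 0 rose, and 0 passed adjusted over the list alone (camera adjusted p = 0.198). The genes of the drug's direct targets differed little: Hdac2 fell by 0.27 on the log2 scale (adjusted p = 0.0473, over 0.05 with DESeq2 size factors or the Wald test), while Hdac1 differed by 0.15 (adjusted p = 0.0622) and Hdac3 by 0.04 (adjusted p = 0.793). Of 22 cholesterol biosynthesis genes, 8 fell and 0 rose, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.00572; adjusted p = 0.14 with an estimated correlation). Insig1, a sterol sensor, fell 1.61-fold.

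Activity-linked genes rose in part. Of 28 immediate early genes 5 rose and 0 fell, also adjusted over the list alone, among them Jun (1.80-fold) and Btg2 (1.83-fold), with camera adjusted p = 0.00321 and adjusted p = 0.446 with an estimated correlation. The most used markers of neuronal activity did not pass: Fos differed by 0.01 (adjusted p = 0.985), Arc by 0.57 (adjusted p = 0.285), Npas4 by 0.31 (adjusted p = 0.488) and Egr1 by 0.21 (adjusted p = 0.442). Of 24 delayed effector genes 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0063; adjusted p = 0.299 with an estimated correlation). They include Ptgs2 and Plk2, a kinase that weakens active synapses (1.47-fold). Bdnf, a neurotrophin, rose from 53.1 ± 10.3 to 70.5 ± 7.29 CPM (SD, n = 4; log2 fold change 0.47, adjusted p = 0.0217), a call lost when single libraries were left out. Of 17 MAP kinase feedback genes 7 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 7.51e-05; adjusted p = 0.166 with an estimated correlation). Dusp6, a phosphatase of ERK, rose 1.80-fold and Rasl11b, a small GTPase gene, 1.73-fold.

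Markers of several cell types moved with the drug. Of 10 oligodendrocyte precursor genes 7 rose and 0 fell, also adjusted over the list alone (median log2 fold change 0.56, camera adjusted p = 7.51e-05; adjusted p = 0.174 with an estimated correlation), with Gpr17 up 1.5-fold and Neu4 1.44-fold. Of 14 choroid plexus genes 11 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.000465; adjusted p = 0.346 with an estimated correlation). This rested on replicates 2 and 4, which held 5433 and 5237 CPM of the choroid plexus marker Ttr against 10.9 CPM or less in replicates 1 and 3; without them the list gave adjusted p = 0.484. Rises were also called, as rose of tested, for endothelial cells and pericytes (6 of 16), nuclear long non-coding RNAs (3 of 10), voltage-gated ion channels (7 of 40), astrocytes (3 of 16), oligodendrocytes (2 of 14), synaptic vesicle genes (1 of 41), GABA signalling (1 of 22), hippocampal excitatory neurons (2 of 18) and glutamate receptors (0 of 45). Adjusted over the list alone these counts were 6, 4, 7, 3, 2, 1, 0, 2 and 0, and the camera adjusted p ran from 0.0015 to 0.0403, or adjusted p = 0.299 to 0.469 with an estimated correlation. The other lists did not pass. They are given here as rose and fell of tested, with the counts adjusted over the list alone in brackets. The signalling lists were histone genes 0 and 2 of 18 [0 and 2], glucocorticoid-responsive genes 2 and 0 of 20 [2 and 0], cAMP and calcium signalling 2 and 0 of 48 [1 and 0], neuropeptides 0 and 0 of 17 [0 and 0]. They also held heat shock genes 1 and 0 of 18 [1 and 0], circadian clock genes 3 and 3 of 18 [4 and 4], and inflammatory genes 0 and 3 of 15 [0 and 3]. The other marker lists were ribosomal proteins 0 and 0 of 38 [0 and 0], mitochondrially encoded genes 0 and 0 of 12 [0 and 0], and medium spiny neurons 2 and 0 of 17 [2 and 0]. The last were interneurons 1 and 0 of 13 [1 and 0], neocortical neurons 0 and 0 of 12 [0 and 0], thalamic neurons 1 and 0 of 12 [1 and 0], microglia 1 and 0 of 15 [0 and 0], and blood 0 and 0 of 5 [0 and 0]. The medium spiny list had median −0.02 and mean 0.03 with an upward test, and the circadian list had median −0.04 with an upward test. Within the clock list, Ciart, a repressor of the clock, fell 3.82-fold, while Arntl rose 1.70-fold and Cry2 1.56-fold.

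In all, 3797 of 18261 genes were called in this comparison, 1355 higher and 2442 lower, with 357 of the first and 308 of the second changed over 2-fold. The share of called genes that were lower was 64.3% with TMM, 76.4% with library size scaling and 48.6% with GC content and length offsets. Without replicates 2 and 4 of the drug group 2358 genes were called, 725 higher and 1633 lower; only replicates 1 and 2 gave 1642, only replicates 3 and 4 gave 1555, and a batch term for these sets 5155.

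**Figure D2:**
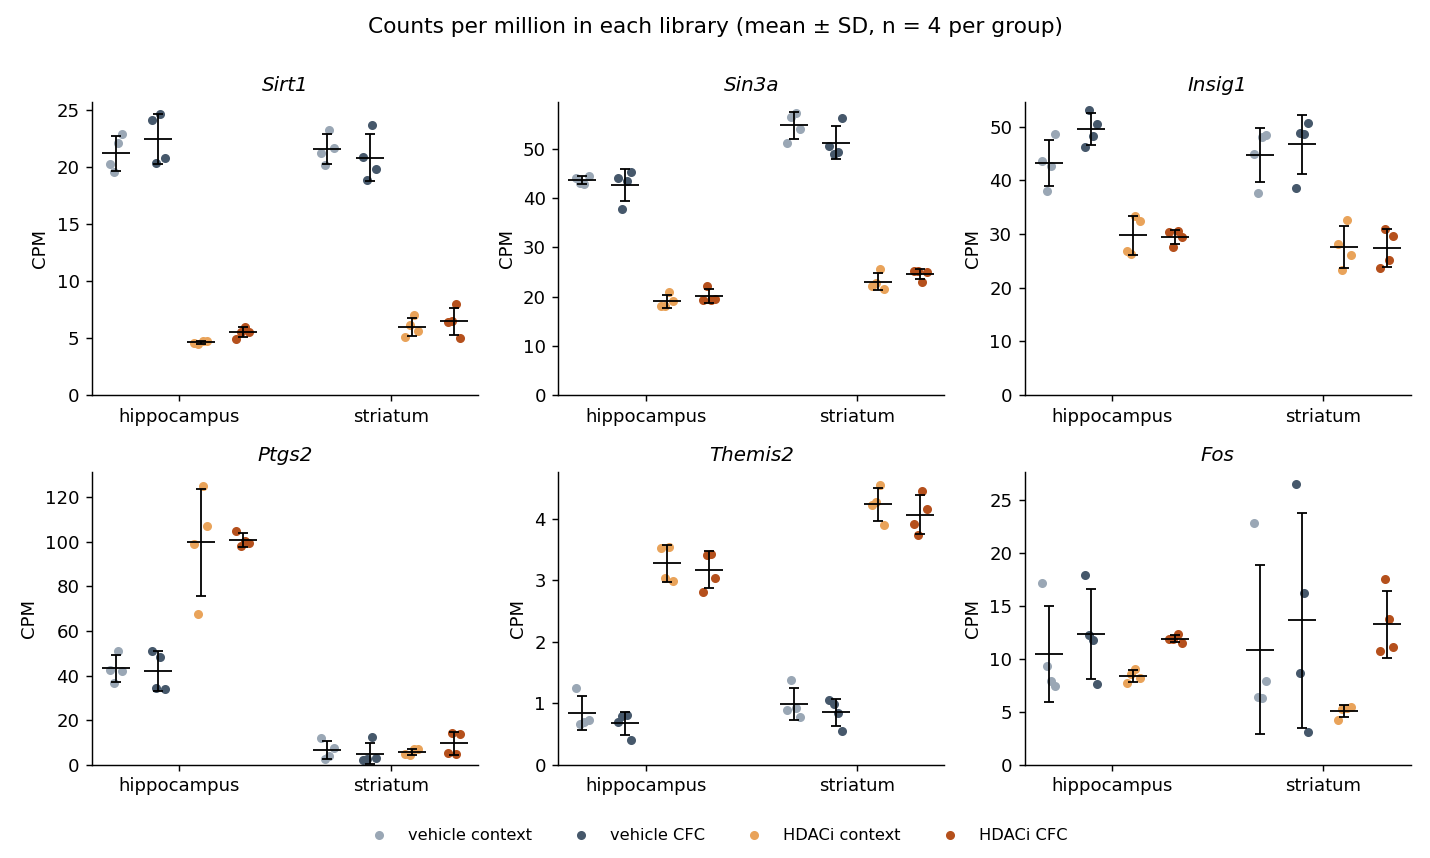
CPM (vertical axes from 0) of 6 genes in each library, with bars for mean ± SD (n = 4). Sirt1, Sin3a and Insig1 were lower and Themis2 higher in all HDACi libraries than in all vehicle libraries of the same region, while the Fos values of the HDACi and vehicle groups overlapped in hippocampus.

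**Figure D3:**
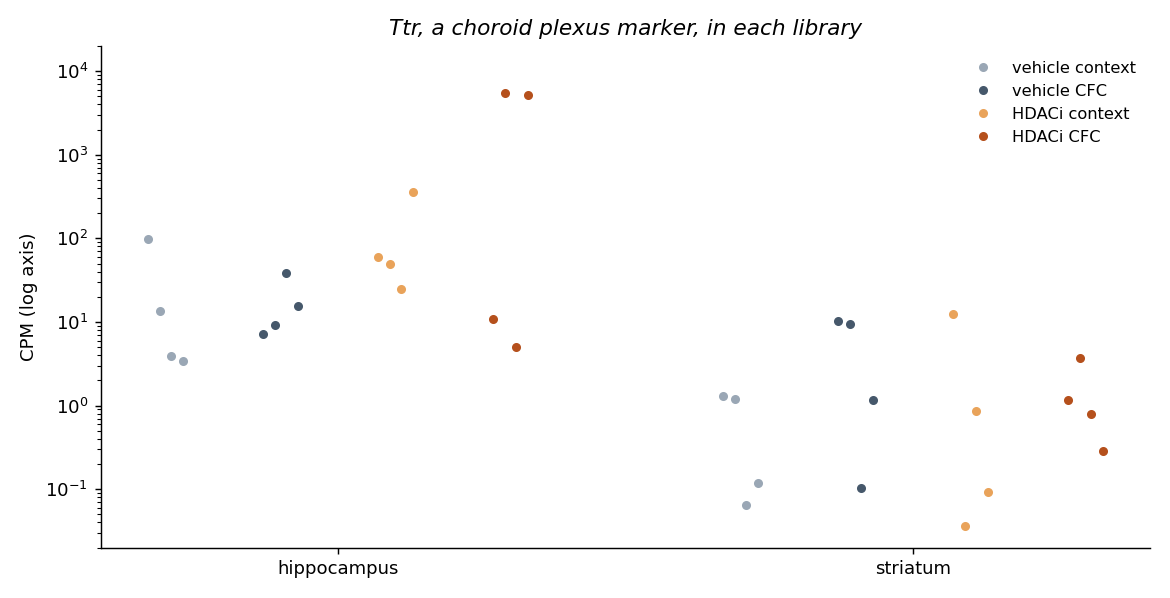
CPM of the choroid plexus marker Ttr in each library (vertical log axis), by region and group. Replicates 2 and 4 of the hippocampus HDACi CFC group, at 5433 and 5237 CPM, stood far above the other hippocampus libraries, which ran up to 355 CPM.

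In hippocampus of context mice Sirt1 fell 4.33-fold, from 21.2 ± 1.54 to 4.63 ± 0.134 CPM (SD, n = 4; log2 fold change −2.11, SE 0.098, adjusted p = 3.49e-09), Sin3a fell 2.16-fold and Ep300 1.62-fold. Kcnj2 (ENSMUSG00000041695; mm10 chromosome 11, 111066164 to 111076821), an inward-rectifier potassium channel gene, rose 3.13-fold, from 15.4 ± 2.18 to 45.5 ± 6.78 CPM (SD, n = 4), and Ptgs2 rose 2.44-fold. Bdnf rose 1.51-fold, from 52.4 ± 4.59 to 74.8 ± 11.8 CPM (SD, n = 4; adjusted p = 0.00541). Prox1, a transcription factor of dentate granule cells, rose 1.60-fold and Tdo2, an enzyme of tryptophan breakdown and dentate marker, 1.70-fold. Fos differed by −0.24 (adjusted p = 0.562) and Arc by 0.49 (adjusted p = 0.387). Hdac1 rose by 0.17 on the log2 scale (SE 0.056, adjusted p = 0.039), with 37.6 ± 1.65 against 35.3 ± 0.862 CPM (SD, n = 4) and the lowest drug library (36.1 CPM) below the highest vehicle library (36.2 CPM). Its call was lost with library size scaling (log2 fold change 0.09, adjusted p = 0.272), without the low-count filter, in each set of 2 replicates, in a fit of the 2 groups alone, and without any 1 of 6 of the 8 libraries. Hdac2 differed by −0.16 (adjusted p = 0.255) and Hdac3 by 0.12 (adjusted p = 0.344).

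Of the 20 called lists 18 rose. The acetyltransferase and reader genes had 10 of 22 lower and 0 higher, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.000463; adjusted p = 0.149 with an estimated correlation). Cholesterol biosynthesis had 6 of 22 lower, also adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.149 with an estimated correlation). MAP kinase feedback genes had 8 of 17 higher and 1 lower (9 and 1 adjusted over the list alone), and oligodendrocyte precursor genes 7 of 10 higher (8 adjusted over the list alone), each with camera adjusted p = 3.01e-06 and adjusted p = 0.092 with an estimated correlation. Hippocampal excitatory neuron markers had 5 of 18 higher (6 adjusted over the list alone; camera adjusted p = 0.000742; adjusted p = 0.149 with an estimated correlation). Glucocorticoid-responsive genes had 5 of 20 higher (8 adjusted over the list alone), with camera adjusted p = 0.00789 and adjusted p = 0.46 with an estimated correlation; Zbtb16 rose 1.58-fold and Ddit4, a brake on mTOR, 1.61-fold. Immediate early genes had 6 of 28 higher and 1 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00398; adjusted p = 0.46 with an estimated correlation). The choroid plexus list did not pass (0 of 14 called, also adjusted over the list alone; camera adjusted p = 0.109), but gave 0.00995 and rose when replicates 2 and 4 of the HDACi CFC group were left out of the shared fit. In all 3612 genes were called, 1196 higher and 2416 lower (66.9% lower; 81% with library size scaling and 51.7% with GC content and length offsets), and 186 of the first and 329 of the second changed over 2-fold. Only replicates 1 and 2 gave 1497, only replicates 3 and 4 gave 1625, and a batch term 5088.

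In striatum after conditioning the drug again raised Themis2 (5.04-fold, to 4.07 ± 0.314 CPM, SD, n = 4). Ccnj, a cyclin gene, fell 4.02-fold, from 10.2 ± 0.435 to 2.4 ± 0.316 CPM (SD, n = 4; log2 fold change −2.01, SE 0.111, adjusted p = 1.44e-08), and Tnfaip3, a brake on NF-kappaB, fell 3.76-fold from 7.22 ± 0.968 CPM. Sin3a fell 1.97-fold and Stat2, a mediator of interferon signals, 1.69-fold. Plk2 rose 1.82-fold to 420 ± 39.6 CPM, Rgs4, a regulator of G protein signals, 1.91-fold to 1876 ± 484 CPM, and Akap5, a postsynaptic kinase anchor, 1.71-fold to 653 ± 110 CPM (SD, n = 4). Fos differed by 0.04 (adjusted p = 0.965), Arc by 0.39 (adjusted p = 0.58), and Hdac1, Hdac2 and Hdac3 by 0.11, −0.12 and −0.05 without passing.

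Of the 19 called lists 18 rose. Oligodendrocyte precursor genes had 8 of 10 higher, also adjusted over the list alone (median log2 fold change 0.62, camera adjusted p = 2.8e-05; adjusted p = 0.274 with an estimated correlation), among them Gpr17 (1.60-fold) and Pdgfra (1.48-fold). Acetyltransferases and readers had 10 of 22 lower and 0 higher, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00621; adjusted p = 0.274 with an estimated correlation). Delayed effector genes had 7 of 24 higher, also adjusted over the list alone, and ion channels 9 of 40 (8 adjusted over the list alone), with camera adjusted p = 0.00768 and 0.00845, each with adjusted p = 0.37 with an estimated correlation. Thalamic neuron markers had 4 of 12 higher, or 5 adjusted over the list alone (camera adjusted p = 0.0153; adjusted p = 0.37 with an estimated correlation). Hippocampal excitatory markers had 3 of 13 higher, also adjusted over the list alone (camera adjusted p = 0.0223; adjusted p = 0.274 with an estimated correlation). Beside these, replicate 2 of the drug group and replicate 3 of the vehicle group held the lowest means of the medium spiny neuron list, 8.11 and 8.14 log2 CPM against 8.38 to 8.85 in the other striatum libraries. The hippocampal excitatory list was highest in replicates 2 and 4 of the drug group, at 3.96 and 3.71 log2 CPM against 1.89 to 3.35 in the other striatum libraries, and replicate 4 stays in the fit without the libraries apart. In that fit the ribosomal protein list (4 of 38 higher, 0 adjusted over the list alone; camera adjusted p = 0.00888; adjusted p = 0.508 with an estimated correlation) gave 0.124. The choroid plexus list (5 of 11 higher, 7 adjusted over the list alone; camera adjusted p = 0.0229; adjusted p = 0.37 with an estimated correlation) gave 0.157. Cholesterol biosynthesis had 4 of 22 lower and 1 higher, also adjusted over the list alone, and did not pass (camera adjusted p = 0.0781), although Hsd17b7, an enzyme of that pathway, fell 1.90-fold. In all 4416 of 18256 genes were called, 1748 higher and 2668 lower (60.4% lower; 76.5% with library size scaling and 50.1% with GC content and length offsets), and 379 of the first and 346 of the second changed over 2-fold. Only replicates 1 and 2 gave 1401, only replicates 3 and 4 gave 2329, and a batch term 5580.

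In striatum of context mice Ing5 fell 3.93-fold, from 24.3 ± 2 to 5.71 ± 0.807 CPM (SD, n = 4; log2 fold change −1.97, SE 0.102, adjusted p = 7.14e-09), and Sin3a 2.2-fold, from 54.8 ± 2.77 to 23.1 ± 1.82 CPM. Themis2 rose 4.62-fold and Lamb3, a laminin chain gene, 3.27-fold. Rgs4 rose 2.03-fold to 2189 ± 185 CPM and Camk1g, a calcium-dependent kinase gene, 2.21-fold to 89.7 ± 13.6 CPM (SD, n = 4). Bcl11b, a transcription factor of medium spiny neurons, rose 1.58-fold, from 237 ± 5.47 to 346 ± 25.5 CPM (SD, n = 4). Hsd17b7 fell 2.01-fold. Fos was 5.10 ± 0.561 against 10.9 ± 8.01 CPM (SD, n = 4; log2 fold change −0.98, adjusted p = 0.172), with all drug libraries (4.26 to 5.44 CPM) below all vehicle libraries (6.35 to 7.94 CPM, and 1 at 22.9 CPM).

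Ion channel genes had 14 of 40 higher and 0 lower, or 18 adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 0.000259; adjusted p = 0.368 with an estimated correlation). Kcna5 rose 1.74-fold and Scn3a 1.47-fold. Nuclear long non-coding RNAs had 8 of 10 higher, also adjusted over the list alone (camera adjusted p = 0.000243; adjusted p = 0.318 with an estimated correlation), with Neat1 up 2.15-fold and Mirg 1.64-fold. Endothelial and pericyte genes had 8 of 16 higher, or 11 adjusted over the list alone (camera adjusted p = 0.000259; adjusted p = 0.368 with an estimated correlation). Astrocyte genes had 7 of 16 higher, or 8 adjusted over the list alone (camera adjusted p = 0.000898; adjusted p = 0.414 with an estimated correlation). Medium spiny neuron markers had 5 of 19 higher, also adjusted over the list alone (camera adjusted p = 0.00516; adjusted p = 0.544 with an estimated correlation). Acetyltransferases and readers had 11 of 22 lower and 1 higher, and cholesterol biosynthesis 7 of 22 lower and 1 higher, both also adjusted over the list alone (camera adjusted p = 0.00305 and 0.019; adjusted p = 0.318 and 0.544 with an estimated correlation). Immediate early genes did not pass as a list (3 higher and 1 lower of 28, 2 and 0 adjusted over the list alone; camera adjusted p = 0.564). In all 4524 genes were called, 1878 higher and 2646 lower (58.5% lower; 78.6% with library size scaling and 50.1% with GC content and length offsets), and 373 of the first and 347 of the second changed over 2-fold. Scaling to library size moved the median of all genes from 0.03 to −0.09, a shift of −0.11. Only replicates 1 and 2 gave 1520, only replicates 3 and 4 gave 2146, and a batch term 5656.

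**Figure D4:**
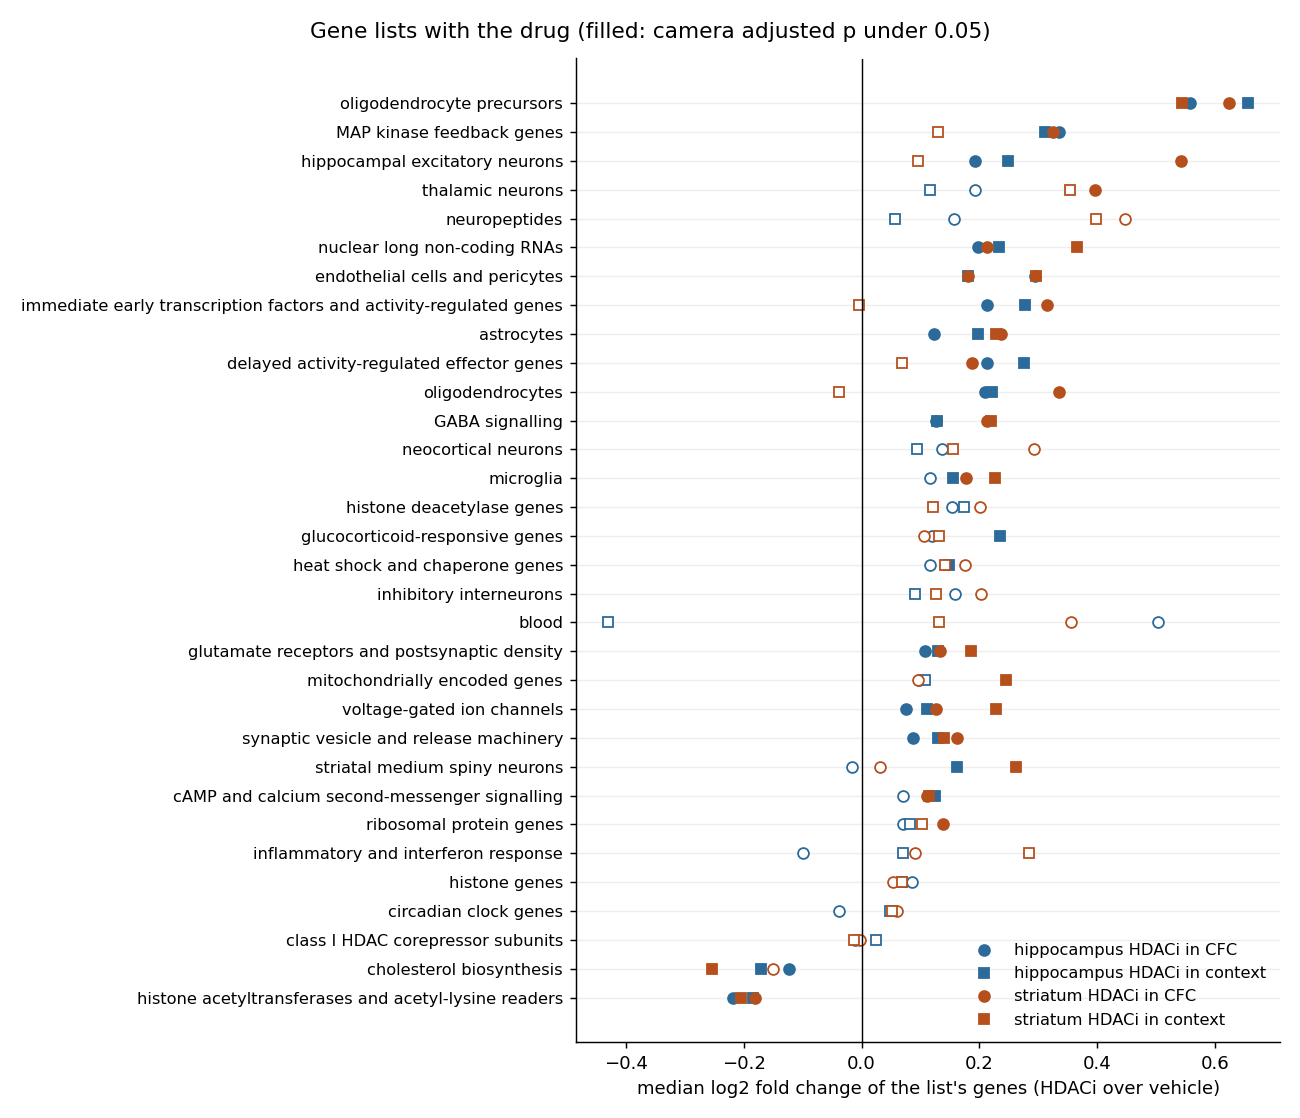
Median log2 fold change (HDACi over vehicle, horizontal axis) of each fixed gene list but the choroid plexus list, in the 4 drug comparisons (symbols); filled symbols mark camera adjusted p under 0.05 with the preset correlation. Acetyltransferases and acetyl-lysine readers lie below 0 and oligodendrocyte precursor genes above 0 in all 4.

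The drug's effects were shared between behaviours and regions. In hippocampus 2797 genes were called after both behaviours, 2796 in the same direction: 763 higher in both against 89 expected by chance and 2033 lower in both against 323. In striatum 3282 were called after both, all in the same direction (1092 higher against 180 expected, 2190 lower against 387). Across regions 2508 genes were called after conditioning (2496 in the same direction) and 2458 in context mice (2446 in the same direction). Over genes, which are not independent replicates, the drug's log2 fold changes correlated between behaviours with Pearson r 0.745 in hippocampus and 0.781 in striatum, and between regions with 0.678 after conditioning and 0.724 in context mice. Same-numbered libraries of both regions may come from the same mouse, and their residuals correlated (r 0.13 to 0.84). The overlap and correlation between regions may be raised by this, by an amount that was not tested.

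The regions differed in the drug's effect on a small set of genes. In context mice Jun, an AP-1 transcription factor (ENSMUSG00000052684; mm10 chromosome 4, 95049034 to 95052222), rose by 0.73 in hippocampus and fell by 0.55 in striatum (log2 difference 1.27, 95% confidence interval 0.80 to 1.74, n = 4 per group, adjusted p = 0.00431). Jph1, a junctophilin that ties the endoplasmic reticulum to the cell membrane, rose by 0.52 in hippocampus and fell by 0.45 in striatum (difference 0.95, SE 0.122, adjusted p = 0.000154). Acat2, an acetyl-CoA acetyltransferase at the start of sterol synthesis, fell by 0.28 in hippocampus and rose by 0.34 in striatum (difference −0.64, adjusted p = 0.00152). Akap5 rose by 0.91 in striatum, with 0.13 in hippocampus (difference −0.79, adjusted p = 0.00561), and Ahr, the aryl hydrocarbon receptor, fell by 1.48 in striatum, with −0.12 in hippocampus (difference 1.34, adjusted p = 0.00157). Of 19198 genes 119 differed between regions in context mice (55 with a higher and 64 with a lower effect in hippocampus), with 208 without the libraries apart and 312 with a mouse block. Leaving out single libraries gave 76 to 162, with 76 without hippocampus vehicle context replicate 2. Immediate early genes (1 of 28 higher, also adjusted over the list alone), MAP kinase feedback genes (0 of 17, 2 adjusted over the list alone) and oligodendrocyte genes (0 of 14, also adjusted over the list alone) had the higher effect in hippocampus, with camera adjusted p = 0.00812, 0.00812 and 0.000811. Each gave adjusted p = 0.885 with an estimated correlation, and the immediate early list gave 0.127 without the libraries apart. The number of lists ran from 1 (without striatum vehicle context replicate 1) to 8 (without hippocampus vehicle context replicate 2).

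After conditioning 51 genes differed between regions in the drug's effect (27 and 24), and 187 with a mouse block. Leaving out single libraries gave 31 to 169, with 31 without hippocampus vehicle replicate 4, 148 without hippocampus HDACi replicate 1, 169 without hippocampus HDACi replicate 3 and 99 without striatum HDACi replicate 2. Ccnj fell by 0.89 in hippocampus and by 2.01 in striatum (difference 1.12, SE 0.148, adjusted p = 0.000532), and Tnfaip3 fell by 0.74 and 1.91 (difference 1.17, SE 0.201, adjusted p = 0.00618). Mylip, a ubiquitin ligase gene, rose by 1.08 in hippocampus, with 0.16 in striatum (difference 0.91, adjusted p = 0.00618). Zc3h12c, an RNA-binding zinc finger gene, fell by 0.46 in hippocampus and rose by 0.76 in striatum (difference −1.22, adjusted p = 0.00166). The choroid plexus list had the higher effect in hippocampus (0 of 14 called, 5 adjusted over the list alone; camera adjusted p = 0.00107; adjusted p = 0.866 with an estimated correlation), and without the libraries apart gave 0.311 in the other direction; the number of lists ran from 0 (without hippocampus HDACi CFC replicate 2) to 5 (without hippocampus HDACi CFC replicate 1). The region difference of the effect of conditioning in vehicle mice gave 0 genes (edgeR; 194 at unadjusted p under 0.05 where 960 are expected by chance; 0 by DESeq2 and 0 with a mouse block), with −0.09 for Fos (95% confidence interval −1.26 to 1.09). There 3 lists passed camera with 0 members called, also adjusted over the list alone: delayed effectors (0.0476), medium spiny neurons (0.000385) and oligodendrocytes (0.0403) had the higher effect in hippocampus, each with adjusted p = 0.936 with an estimated correlation. Without the libraries apart the last 2 gave 0.303 and 0.558, oligodendrocytes in the other direction. The number of lists ran from 2 (without hippocampus vehicle context replicate 3) to 11 (without striatum vehicle context replicate 4).

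**Figure D5:**
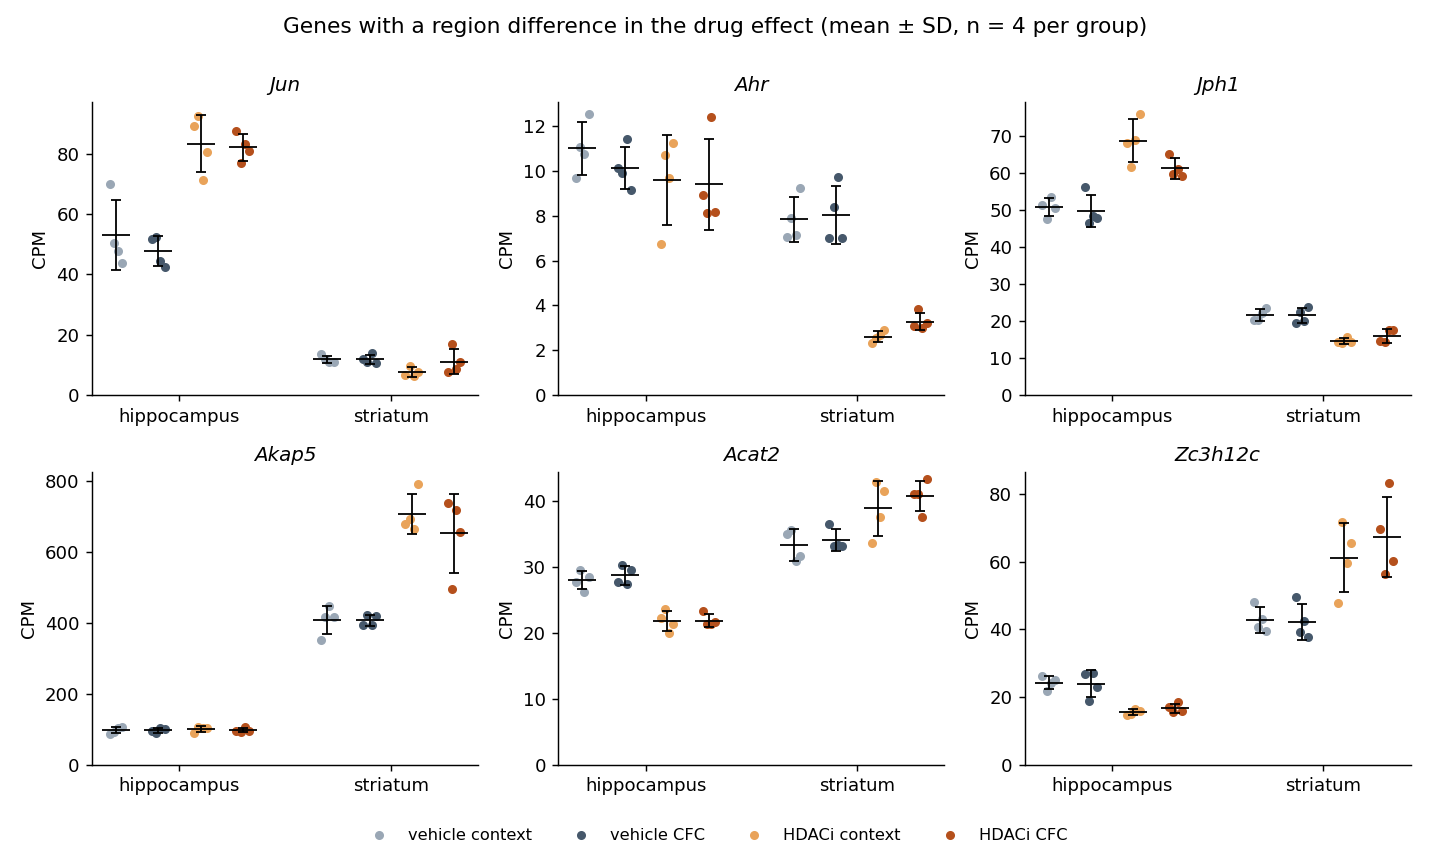
CPM (vertical axes from 0) of 6 genes with a region difference in the drug's effect in context mice, in each library, with bars for mean ± SD (n = 4). Akap5 was higher with the drug in striatum and near 100 CPM in all hippocampus groups, and Ahr was lower with the drug in all striatum libraries.

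Conditioning itself changed 0 genes past the threshold in hippocampus of vehicle mice. Fos was 12.4 ± 4.24 CPM after conditioning and 10.5 ± 4.53 CPM in context mice (SD, n = 4), a log2 fold change of 0.24 (95% confidence interval −0.27 to 0.74). Arc gave 0.13 (−0.61 to 0.86), Npas4 0.47 (−0.12 to 1.05), Egr1 0.08 (−0.28 to 0.45) and Bdnf 0.01 (−0.28 to 0.30). At unadjusted p under 0.05 there were 188 genes where 913 are expected by chance, a shortfall that does not show absence of an effect. The main fit holds no batch term, so the difference between the replicate sets (6528 genes called in hippocampus) stays in its residual spread. That may make these p values too large, which was not tested. DESeq2 called 1, 5830444B04Rik (−1.89, adjusted p = 0.048), named after its value was seen. In drug-treated mice the count was also 0 by edgeR (775 at unadjusted p under 0.05; 0 by DESeq2), and Fos was 11.9 ± 0.354 against 8.37 ± 0.567 CPM (SD, n = 4; log2 fold change 0.49, 95% confidence interval −0.02 to 1.00). The interaction of drug and conditioning gave 0 genes (390 at unadjusted p under 0.05; 1 by DESeq2, again 5830444B04Rik at 2.49, adjusted p = 0.0204), with 0.25 for Fos (−0.47 to 0.97). All counts were 0 also with a batch term. Cage is tied to behaviour in these contrasts.

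Some lists passed camera in these contrasts without 1 called member. In hippocampus of vehicle mice 8 lists passed with 0 members called, also adjusted over the list alone; the number of lists ran from 3 to 11 with single libraries left out (3 without vehicle context replicate 3, 11 without vehicle context replicate 1). Glucocorticoid-responsive genes (median 0.11, adjusted p = 0.00724), cholesterol biosynthesis (0.0135), ribosomal proteins (0.0257) and medium spiny markers (0.00456) were higher as lists. Blood genes (median −0.63, adjusted p = 1.75e-08), ion channels (0.00456), nuclear long non-coding RNAs (0.0363) and endothelial genes (0.00456) were lower, with adjusted p = 0.0886 to 0.895 with an estimated correlation over the 8; without the libraries apart ribosomal proteins gave 0.0608. In drug-treated mice choroid plexus genes were higher (median 3.12, adjusted p = 9.88e-13; adjusted p = 0.509 with an estimated correlation; 0 of 14 called, 11 adjusted over the list alone), and the list was lower instead (adjusted p = 9.1e-05) without replicates 2 and 4. Ion channels (0.00103), cAMP and calcium signalling (0.0304) and hippocampal excitatory markers (0.0494) were lower with 0 members called, also adjusted over the list alone, and adjusted p = 0.509 to 0.63 with an estimated correlation; without those libraries each gave 0.517. The number of lists ran from 3 (without HDACi CFC replicate 2) to 13 (without HDACi context replicate 3) there, and from 4 (without vehicle context replicate 4) to 13 (without vehicle context replicate 1) for the interaction. For the interaction, medium spiny markers were lower (median −0.19, adjusted p = 0.00075; adjusted p = 0.0347 with an estimated correlation). Lower too were hippocampal excitatory markers (0.00583), cAMP and calcium signalling (0.0159), glucocorticoid-responsive genes (0.0211) and clock genes (0.0312), and choroid plexus (3.34e-11) and blood genes (1.16e-06) were higher, with adjusted p = 0.261 to 0.868 with an estimated correlation. All 7 had 0 members called, also adjusted over the list alone, and without the libraries apart the medium spiny list gave 0.019, the choroid plexus list 0.000527 in the other direction, and the other lists 0.138 or more.

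In striatum conditioning also changed 0 genes past the threshold. In drug-treated mice Fos was 13.3 ± 3.17 CPM after conditioning and 5.10 ± 0.561 CPM in context mice (SD, n = 4), a log2 fold change of 1.34 (95% confidence interval 0.27 to 2.39, adjusted p = 0.839). Arc was 152 ± 39.2 against 86.9 ± 24.2 CPM (SD, n = 4; 0.77, −0.21 to 1.75). Here 28 immediate early genes were higher as a list (median 0.45, camera adjusted p = 2.36e-09; adjusted p = 0.409 with an estimated correlation), with 0 called, also adjusted over the list alone. Oligodendrocyte genes (median 0.22, 7.95e-07), MAP kinase feedback genes (0.0104), delayed effectors (0.0342), cholesterol biosynthesis (0.0305), ribosomal proteins (0.0234), oligodendrocyte precursors (0.0104), hippocampal excitatory markers (0.0122) and choroid plexus genes (0.0126) were higher too. Medium spiny markers (median −0.24, 1.44e-10), mitochondrially encoded genes (0.00096), endothelial genes (0.00125), nuclear long non-coding RNAs (0.00214) and ion channels (0.0234) were lower. All 14 lists had 0 members called, also adjusted over the list alone, and adjusted p = 0.3 to 0.633 with an estimated correlation; without the libraries apart cholesterol biosynthesis (0.802), mitochondrially encoded genes (0.0734), choroid plexus genes (0.183) and ion channels (0.371) did not pass. HDACi CFC replicates 2 and 4 held medium spiny means of 8.11 and 8.44 log2 CPM, against 8.68 to 8.85 in the other drug libraries of striatum. Their hippocampal excitatory means were 3.96 and 3.71, against 2.34 to 3.03. The fit without the libraries apart keeps replicate 4, so tissue composition is not excluded as a part of these list shifts. By edgeR 988 genes had unadjusted p under 0.05 (913 expected), and DESeq2 called 2, Gm26645 (−0.95, adjusted p = 0.00458) and Gm6556 (−1.02, adjusted p = 0.00167), named after their values were seen. Leaving out HDACi CFC replicate 1 made edgeR call Gm6556 alone (−1.25, adjusted p = 0.0306).

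In vehicle mice the striatum gave Fos 13.6 ± 10.1 against 10.9 ± 8.01 CPM (SD, n = 4; 0.32, 95% confidence interval −0.70 to 1.34), with 0 genes called (216 at unadjusted p under 0.05; 0 by DESeq2). Oligodendrocyte genes were lower as a list (median −0.11, adjusted p = 0.000502), blood genes lower (4.08e-05) and choroid plexus genes higher (0.00243), with 0 members called, also adjusted over the list alone. They gave adjusted p = 0.947 with an estimated correlation; oligodendrocytes gave 0.741 and blood 0.0731 without the libraries apart. The number of lists ran from 2 (without vehicle CFC replicate 2) to 11 (without vehicle CFC replicate 1). The interaction gave 0 genes (380 at unadjusted p under 0.05; 0 by DESeq2), with 1.01 for Fos (−0.45 to 2.48) and 0.52 for Arc. As lists, immediate early genes (median 0.35, adjusted p = 4.27e-06), delayed effectors (0.00828), MAP kinase feedback genes (0.0191), oligodendrocytes (median 0.33, 3.04e-12), oligodendrocyte precursors (0.00972) and hippocampal excitatory markers (0.00907) were higher. Medium spiny markers (6.95e-05), ion channels (0.0363), mitochondrially encoded genes (0.00118), nuclear long non-coding RNAs (0.00347) and endothelial genes (0.0114) were lower. All 11 had 0 members called, also adjusted over the list alone, and adjusted p = 0.216 to 0.632 with an estimated correlation; without the libraries apart ion channels (0.866), mitochondrially encoded genes (0.322), oligodendrocyte precursors (0.748) and endothelial genes (0.0522) did not pass. That fit again keeps HDACi CFC replicate 4, so tissue composition is not excluded here either. The number of lists ran from 3 (without HDACi CFC replicate 2) to 15 (without HDACi CFC replicate 3).

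As a baseline, hippocampus and striatum of vehicle context mice differed in 8471 of 19198 genes, 4647 higher in hippocampus and 3824 higher in striatum, and in 10325 with a mouse block. Drd1, a dopamine receptor gene of medium spiny neurons, was 2.88 ± 0.390 CPM in hippocampus and 372 ± 6.25 CPM in striatum (SD, n = 4; log2 fold change −7.04), and Penk, the enkephalin precursor, 22.8 CPM against 1343 ± 128 CPM. Dsp, a desmosomal gene of dentate granule cells, was 101 ± 12.4 against 0.430 ± 0.133 CPM (7.84), and Prox1 180 ± 16.3 against 16.2 ± 2.43 CPM (3.44). All 19 medium spiny markers tested were lower in hippocampus, also adjusted over the list alone (camera adjusted p = 6.03e-106; adjusted p = 2.59e-06 with an estimated correlation). Of 18 hippocampal excitatory markers 15 were higher and 1 lower, also adjusted over the list alone (2.23e-23; adjusted p = 6.25e-06 with an estimated correlation). All 14 oligodendrocyte genes were lower in hippocampus, also adjusted over the list alone (median −0.90, camera adjusted p = 0.000262; adjusted p = 0.551 with an estimated correlation). Clock genes (2 higher and 12 lower of 18, also adjusted over the list alone; 0.00512), mitochondrially encoded genes (0 and 8 of 12, 0 and 9 adjusted over the list alone; 0.0356) and delayed effectors (5 and 12 of 24, 5 and 14 adjusted over the list alone; 0.035) were lower, with adjusted p = 0.239, 0.794 and 0.553 with an estimated correlation. The cAMP and calcium list (21 and 20 of 48, 22 and 20 adjusted over the list alone) tested lower (0.00572) with a median of 0.14 and a mean of −0.31. Neuropeptides (8 and 4 of 18, 8 and 6 adjusted over the list alone) tested lower (0.0356) with a median of 0.82 and a mean of 0.40. With an estimated correlation these gave adjusted p = 0.327 and 0.553.

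Counts of some named genes are uncertain, since another annotated gene overlaps them: on the other strand for Sirt1, Sin3a, Jun, Bdnf, Prox1, Rcor3, Gpr17, Pdgfra, Arntl, Cry2, Ahr, Jph1, Zc3h12c, Hyls1, Ccnyl1, Penk and Dsp, and on the same strand for Ep300, Pdgfra, Neat1 and Mirg.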

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

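Chosen only after the result was seen were the tests of the drug as the source of the surplus of lower genes, of a drug effect on hippocampal cells behind the choroid plexus genes, and the shuffled control for the offsets.

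In context mice 119 genes and after conditioning 51 genes differed between the regions in the drug's effect, by a test of the difference itself. Named in both were 8 genes, given here as the hippocampal minus the striatal log2 effect after conditioning and in context mice: Ahr 1.17 and 1.34, Tnfaip3 1.17 and 0.88, Hyls1 0.97 and 1.26, Akap5 −0.70 and −0.79, Acat2 −0.67 and −0.64, Zc3h12c −1.22 and −1.20, Ccnyl1 −0.99 and −1.05, and Zfp959 −1.001 and −1.15. Ahr and Tnfaip3 thus fell more in striatum, and Akap5 rose more in striatum. For context mice 1 of 35 splits called as many genes (119 against at most 0 in the others), in the fit without a mouse block. The other splits mix drug and vehicle mice, so the drug's effect shared by both regions adds to their spread and may lower their calls. That comparison therefore cannot decide on chance for a region difference. After conditioning 4 of 35 splits called as many (51, with 135 in the highest other split), so chance cannot be excluded there for the fit without a mouse block. With that block 312 genes in context mice and 187 after conditioning were called, and no splits of the blocked fit were compared.

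Single libraries lay far from the other 3 of their group in 8 of 136 measures tested, where chance alone gives about 1 in 20 groups, or 6.8. In striatum vehicle context replicate 1 held 22.9 CPM of Fos (others 6.35 to 7.94) and 203 CPM of Arc (60.6 to 76.0), so both activity markers stood high in the same mouse. In striatum HDACi context replicate 1 held 4.26 CPM of Fos (5.32 to 5.44). In striatum vehicle CFC replicate 3, which also stood apart by its low medium spiny markers, held 17.4 CPM of Bdnf (0.210 to 0.656), and in striatum vehicle context replicate 3 held 17.4 CPM of Hdac1 (14.9 to 15.1). In hippocampus vehicle context replicate 3 held 244 CPM of Homer1 (192 to 201). The hippocampal excitatory neuron list averaged 6.08 log2 CPM in hippocampus HDACi context replicate 1 (5.88 to 5.91). In hippocampus HDACi CFC replicate 3 changed by −0.152 log2 per 10 points of GC content (0.109 to 0.159).

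Choroid plexus genes were high in replicates 2 and 4 of the hippocampus HDACi CFC group, with Ttr at 5433 and 5237 CPM and a mean log2 excess of the 14 list genes of 4.20 and 4.03. Of the 14 genes 0 are in another list. The tables argue against an effect of the drug with conditioning on hippocampal cells in all mice of the group, since the other 2 libraries held at most 10.9 CPM of Ttr, below the median of 20.1 CPM in the 12 libraries of the other hippocampal groups (3.44 to 355). Choroid plexus tissue in the sample may be the source: the excess across the list genes correlated with that of the vehicle library with most Ttr (context replicate 1, 98.1 CPM, mean excess 0.38) with r 0.783 and 0.8. That met neither the bound set for this source, r over 0.8, nor the bound against it, r under 0.5, so tissue carried along and other sources of this excess cannot be told apart.

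With the drug more genes were lower than higher. Of the genes called lower after conditioning, 99.6% in hippocampus and 99.7% in striatum had a negative log2 fold change in context mice, which share no library (for higher genes 96.6 and 99.1%), as an effect of the drug may give. The share of lower genes was 58.4% or more with library size scaling and DESeq2 size factors, over the bound of 55% set for scaling not being the source. That bound was too narrow, since offsets from shuffled GC content and length gave 51.6 to 57.0% lower by centring alone, so scaling cannot be told apart. Offsets from the real values gave 48.6% at the lowest, but the same centring moves that value, so a GC content and length trend cannot be told apart from the drug for this surplus either.

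Over the groups together replicates 1 and 2 differed from 3 and 4, by 6528 genes in hippocampus and 3739 in striatum. This did not hold in each group: the closest pair was replicates 2 and 4 in hippocampus HDACi CFC (chi-square per degree of freedom 5.77) and striatum vehicle CFC (11.5), and replicates 1 and 3 in striatum HDACi CFC (14.4). The log2 differences between the 2 sets correlated across regions with r 0.865 over 10283 genes. This argues against dissection of each sample as the only source. A GC content trend shared by both regions can give such an r, so dissection as a part of the split is not excluded. The differences followed GC content (Spearman rho −0.837 in hippocampus and −0.786 in striatum). After GC content and length offsets 1862 genes (28.5%) were left in hippocampus and 675 (18.1%) in striatum, between the bounds of 10% and 50% set in advance. A GC content trend of the libraries may thus account for part of the split, and what remains cannot be told apart; a biological difference between the mice of the 2 sets was not tested.

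Other splits of the libraries were compared for each gene count. For the drug in hippocampus after conditioning 1 of 35 splits, the real one, called as many genes (3797 against at most 0). In context mice it was 1 of 35 too (3612 against 2481, from the split into replicates 1 and 2 against 3 and 4). With the batch term 5088 genes were called there. In striatum it was 1 of 35 after conditioning (4416 against 255) and in context mice (4524 against 0). That share is the smallest 35 splits can give and was not adjusted over the contrasts. Splits that mix drug and vehicle mice hold the drug's effect in their spread, which may lower their calls. The splits alone therefore cannot exclude chance. The drug comparisons after conditioning and in context mice share no library. Of genes called in both, 2796 of 2797 in hippocampus and all 3282 in striatum had the same direction. This argues against chance for these genes. For the baseline 1 of 35 splits called as many (8471 against 1886), again the smallest share possible and without adjustment. The 35 splits also ignore a pairing of same-numbered libraries. Among the 8 splits that part all such libraries the highest other called 1 gene, but 8 splits are too few to fall under 0.05. For the contrasts with 0 genes by edgeR every split calls as many, so the comparison says nothing about chance, and only the highest other split is informative. For conditioning in hippocampus these were 35 of 35 splits with vehicle (highest other 5, from replicates 1 and 2 against 3 and 4) and 35 of 35 with the drug (26). For conditioning in striatum they were 35 of 35 with vehicle (1794, from the same split) and 35 of 35 with the drug (1). For the interactions they were 50 of 50 in hippocampus (6569) and 50 of 50 in striatum (3708), counts that point to a structure of the samples other than the interaction, and for the region difference in conditioning 35 of 35 (0). With unadjusted p under 0.05 these 7 contrasts had 188, 775, 216, 988, 390, 380 and 194 genes, and DESeq2 called 1, 0, 0, 2, 1, 0 and 0. The main fits leave the difference between the replicate sets in the residual spread, so these counts may be too low.

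For the number of lists called by camera, 1 of 14 contrasts had under 0.05 of its splits with as many: conditioning in drug-treated striatum (1 of 35 splits, 14 lists against 13). The margin was 1 list, and 1 such result among 14 contrasts without adjustment can arise by chance. Chance is thus not excluded for that number either. Single libraries left out gave 11 to 15 lists (11 without striatum HDACi CFC replicate 2 or 4), without the libraries apart 12 lists passed and 4 of the 14 did not, and 0 passed with an estimated correlation. In hippocampus chance cannot be excluded for the drug after conditioning (6 of 35; 16 against 19) or in context mice (4 of 35; 20 against 27), for conditioning with vehicle (21 of 35; 8 against 16) or the drug (24 of 35; 4 against 13), or for the interaction (38 of 50; 7 against 14). In striatum it cannot be excluded for the drug after conditioning (2 of 35; 19 against 19) or in context mice (6 of 35; 15 against 23), for conditioning with vehicle (34 of 35; 3 against 17) or for the interaction (10 of 50; 11 against 13). Nor can it for the region differences of the drug after conditioning (34 of 35; 1 against 14) and in context mice (24 of 35; 3 against 10), or of conditioning (34 of 35; 3 against 14). For the baseline 17 of 35 splits called as many lists (8 against 13), but a number of lists does not measure the medium spiny and hippocampal excitatory lists, which passed with an estimated correlation too (adjusted p = 2.59e-06 and 6.25e-06).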

How the results depend on the processing

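The batch term, the fits to replicates 1 and 2 or 3 and 4, the offsets, library size scaling and the fit without libraries apart were chosen only after the data were seen. Each drug comparison kept its call count within 1.5 times the main count under DESeq2 size factors, the Wald test, no filter, the replicate block (5419, 5304, 5367 and 5530 genes) and the batch term. GC content and length offsets gave 5825 and 5809 genes in hippocampus. Without the libraries apart hippocampus after conditioning gave 2358 genes (725 higher, 1633 lower). With 2 libraries per group the counts were lower: only replicates 1 and 2 gave 1642 and 1497 in hippocampus and 1401 and 1520 in striatum, and only replicates 3 and 4 gave 1555 and 1625, and 2329 and 2146. Leaving out single libraries gave 2969 to 3769, 2899 to 3507, 3646 to 4707 and 3714 to 4040 for the 4 drug comparisons, 7779 to 8442 for the baseline and 121 to 152 for the fixed lists together. Within single comparisons the number of lists moved more: 3 to 11 for conditioning with vehicle, 3 to 13 with the drug and 4 to 13 for the interaction in hippocampus, 2 to 11 with vehicle and 3 to 15 for the interaction in striatum, and 0 to 5, 1 to 8 and 2 to 11 for the region differences of the drug after conditioning, in context mice and of conditioning. The gene count ran from 0 to 1 for the hippocampal interaction (1 without vehicle context replicate 3) and 0 to 1 for conditioning in drug-treated striatum (1 without HDACi CFC replicate 1). The Wald test called 1 gene for conditioning with vehicle and 1 for the interaction in hippocampus, and 2 for conditioning with the drug in striatum. Region differences after conditioning were 153 by the Wald test, 187 with the replicate block, 134 with the batch term, 305 with offsets and replicate block, and 31 to 169 with single libraries left out (31 without hippocampus vehicle CFC replicate 4, 148 and 169 without hippocampus HDACi CFC replicates 1 and 3, 99 without striatum HDACi CFC replicate 2). In context mice they were 199, 312, 223, 440 and 76 to 162, with 73 without the filter and 208 without the libraries apart; 76 came without hippocampus vehicle context replicate 2. Of the 132 called fixed lists 3 passed with an estimated correlation. The correlation of the drug's effects in hippocampus moved from 0.745 to 0.839 for genes over 3 log2 CPM, and with single libraries left out ran from 0.686 to 0.766 in hippocampus and 0.616 to 0.806 in striatum. Of 497 named calls, 495 were kept with DESeq2 size factors, 492 with the replicate block, 496 with the batch term, 455 without the filter, 434 with library size scaling, 442 without the libraries apart and 391 in every fit that left out 1 library. Only replicates 1 and 2 kept 187 of 347, only replicates 3 and 4 kept 226 of 347, and only the 2 groups compared kept 307 of 345. The direction reversed once: without the libraries apart Aqp1 in hippocampus after conditioning was −0.73 (adjusted p = 0.653). Fewer libraries lower the counts with 2 libraries per group; the cause was not tested for the other changes. No alternative varied the depth, so what it limits was not tested; on simulated counts 2 to 22% of the genes with the smallest simulated fold within a region were called.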

Other observations

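Chosen only after the result was seen was the test of the zinc finger genes, with the families compared beside it and their values without the libraries that stood apart.

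The drug lowered gene families of transcription, nuclear transport and the centrosome together. Of 374 zinc finger genes whose symbol begins with Zfp, which encode DNA-binding proteins, 223, 219, 219 and 219 fell and 12, 10, 16 and 17 rose (hippocampus after conditioning and in context mice, then striatum likewise). Their median log2 fold changes of −0.44, −0.45, −0.45 and −0.44 lay below all of 10000 random lists of the same expression (0% lower in each), and stayed below 0 with library size scaling (−0.55 to −0.51) and with GC content and length offsets (−0.40 to −0.35). Reads shared between near-identical members may move single Zfp genes. Of 20 Nup genes of the nuclear pore 14, 12, 14 and 14 fell, of 21 Taf genes of the TFIID complex 14, 12, 14 and 13 fell and 0 rose, and of 36 Cep genes of the centrosome 14, 16, 18 and 18 fell. Of 40 Zbtb transcription factor genes 15, 18, 13 and 17 fell. Of 92 families and biotypes, 8 lay below the random lists in all 4 comparisons (the Gtf, Ddx and Eif genes too) and 4 above. The smallest p the random lists can give is 0.0002, and 368 relations were adjusted together. That p compares genes, not mice, and takes no account of correlation between the genes of a family. It therefore does not measure the spread between mice.

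Families that lay above the random lists in all 4 were the Sox transcription factors (18 genes, medians 0.23, 0.16, 0.50 and 0.35), collagens (41 Col genes, medians 0.36, 0.19, 0.24 and 0.28, with 8, 1, 3 and 4 called higher and 0 lower), lincRNAs (581 genes, 76, 90, 96 and 133 higher against 37, 37, 33 and 27 lower) and processed transcripts (284 genes, 37, 47, 51 and 71 higher against 9, 11, 15 and 10 lower). The collagen values move with the libraries that stood apart, among them those with choroid plexus genes: without them the medians were 0.12, 0.18, 0.12 and 0.25, with 0, 2, 0 and 5 called higher. The Sox medians were then 0.21, 0.16, 0.33 and 0.32 and the Zfp medians −0.42, −0.45, −0.47 and −0.46. In hippocampus after conditioning counts were lower in that fit, which has 2 fewer libraries: 50 lincRNAs were higher and 29 lower, 25 processed transcripts were higher and 5 lower, and 9 Nup and 9 Taf genes fell.

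Whether longer genes fall more was tested and is argued against: Spearman rho of genomic span and drug effect was 0.066 to 0.107. Neither was the fall a property of genes of low expression (rho −0.06 to 0.018). The relation is not steady. Of called genes under 1 mean log2 CPM 42, 48.6, 36.4 and 31.7% were lower, at 1 to 3 64.6, 72.2, 62.6 and 59.9%, at 3 to 5 80.7, 83.8, 81.2 and 79.5%, at 5 to 7 63.3, 63.7, 57.2 and 58.7%, and over 7 4.0, 1.7, 0.3 and 0.9%.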
